A study of Homo sapiens with 16 samples.

How the data were processed

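RNA and ribosome footprints were measured in PC9, a human lung adenocarcinoma line with an activating EGFR deletion. Of the 4 lines, 2 form the resistant line experiment: DDPr, a cisplatin-resistant derivative kept in 6.6 µM cisplatin and then grown drug-free for 1 week, and Nor, the parental line. The other 2 form the knockdown experiment: sheIF4E2, cells carrying a hairpin against EIF4E2, and shScramble, cells carrying a non-targeting hairpin. Each line had 2 biological replicates, and those of sheIF4E2 carried 2 distinct hairpins. Every culture gave an Input library (fragmented RNA of 40 to 60 nt) and a Ribo library (footprints of 30 nt left after RNase I digestion), 16 libraries in all. Cells received fresh medium 2 h before harvest and cycloheximide at 100 µg/mL for 5 min.

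The deposited tables hold raw read counts per gene and library, as whole numbers with different totals, and the authors applied no normalization to them. The submitters' notes name cutadapt 2.8, Bowtie2 2.3.5.1, HISAT2 2.2.1, SAMtools 1.21, featureCounts 2.0.6 and DESeq2, without giving the role of each, and the build GRCh38. The headers carry the columns that featureCounts writes. Intervals were exon-level in both tables of the resistant line and in the knockdown Input table. The part of the knockdown Ribo table used here held protein-coding and immune receptor genes only, with shorter intervals like those of coding sequence, though the labels do not name the counted feature. Non-coding genes of the knockdown footprints were thus not analysed, and footprint or efficiency comparisons between the experiments rest on different counted regions. Coordinates and lengths used here are those of the exon-level tables.

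Each knockdown table was found to hold 2 stacked lists of genes. The first list covers 62756 rows of the Input table and 20483 rows of the Ribo table. Of genes with unequal groups in both lists, 98.1% in Input and 17.1% in Ribo had equal counts once the control and knockdown columns were exchanged. Only the first list, which sits under the header and in which EIF4E2 is lower under its hairpins, was used, with its columns as labelled, so every knockdown direction below rests on that reading. The gene ANK2 was broken over 3 lines in each table and was left out.

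Total counts were 1603635 to 2110338 in the Input and 531737 to 576996 in the Ribo libraries of the resistant line experiment. They were 807605 to 2484833 in the Input and 392160 to 546192 in the Ribo libraries of the knockdown. Protein-coding genes took 40.5 to 48.0% of the counts in the resistant line Input libraries and 42.2 to 48.2% in its Ribo libraries, against 46.9 to 50.0% in the knockdown Input libraries. Reads carried no molecular identifiers, so exact counting intervals and floors cover counting error only. A fold against a group with no reads was bounded with a floor of 3 counts over the group's 2 libraries.

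Changes were tested with edgeR 4.0.16 quasi-likelihood fits in R 4.3.3, with TMM scaling and the filterByExpr defaults (minimum count 10, minimum total 15). RNA and footprints were each fitted over 4 libraries. Translational efficiency was the change in footprints minus the change in RNA, tested as an interaction over the 8 libraries of an experiment with TMM factors within each assay. All p-values were adjusted by Benjamini-Hochberg over the genes tested, and a gene was called at an adjusted p under 0.05. Changes are log2 fold changes with their standard error (SE), and levels are counts scaled by effective library size (CPM) with the standard deviation (SD) over 2 libraries. With n = 2 per group, the spread of each gene was moderated across genes by the tool.

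In all, 32 gene lists fixed before the data were examined were tested with camera in limma 3.58.1 at its preset correlation of 0.01, adjusted over the lists of a comparison. Lists with under 5 tested members got counts only. The lists cover translation (cap-binding and eIF4F factors, eIF4E2 partners and mRNA repression, eIF4E2-regulated mRNAs from the literature, cytosolic ribosomal proteins, aminoacyl-tRNA synthetases) and platinum damage and handling (nucleotide excision repair, Fanconi and homologous recombination, mismatch repair, platinum transport, metallothioneins, NRF2 and glutathione). Stress and death lists were p53 target genes, the integrated stress response, the unfolded protein response, the BCL2 family and death regulators, and the proteasome. Signalling and metabolism lists were EGFR-MAPK signalling and feedback, interferon-stimulated genes, NF-kB and cytokine genes, hypoxia and HIF targets, glycolysis, nuclear-encoded oxidative phosphorylation, mitochondrially encoded genes and cholesterol synthesis. Cell cycle lists were G1/S and replication, G2/M and replication-dependent histones. Cell identity lists were epithelial markers, mesenchymal markers, lung adenocarcinoma lineage, squamous and neuroendocrine lineage, and other cell types (fibroblast, endothelial, blood).

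Named genes were chosen by a rule fixed before the data were examined. It takes EIF4E2 and, per comparison, the 5 called protein-coding genes with the largest increase and the 5 with the largest decrease. These needed a mean of at least 10 CPM in the higher group (for translational efficiency, in each assay) and both libraries of 1 group beyond both of the other. It also takes up to 2 called members per direction of each list described, or the 2 most counted where none was called, all called cap-binding factors, and the 5 shared calls per direction with the largest smaller change. Genes named outside this rule are marked as chosen after their values were seen.

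Overlap between the experiments was tested with a one-sided Fisher exact test per direction among genes tested in both. The difference of the 2 changes was tested as a contrast over 8 libraries, or 16 for translational efficiency. Windows of 20 neighbouring protein-coding genes were placed along each chromosome after the gene changes had been seen.

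The pipeline was tested on simulated data, in which 200 genes were changed 1.5-, 2- or 4-fold. Of the genes changed 4-fold, 95.5% were recovered in RNA and 40.9% in footprints at the spread of the resistant line, and 98.5% in both at that of the knockdown. Alternatives set before the data were examined were DESeq2 1.42.0, 2 other scalings, 2 other count filters, a replicate block, a fit joining both assays, leaving out each replicate, and, for lists, an estimated correlation and fry. A fit of protein-coding genes alone, the counts of genes called in both RNA and footprints, and the left-out replicates for lists, overlaps and differences, were added after the data had been seen. Tables were read with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots were drawn with matplotlib 3.10.9. Base composition of genes was not used here.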

Results

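The series asks how loss of eIF4E2, a cap-binding protein that can hold back translation, relates to cisplatin resistance in lung cancer cells. RNA (Input) and ribosome footprints (Ribo) were counted in 8 cultures of PC9, 2 per line, which gave 16 libraries. In the resistant line, DDPr, the Input libraries of replicates 1 and 2 held 2046458 and 2017707 counts and the Ribo libraries 550886 and 531737. In its parental line, Nor, they held 2110338 and 1603635 in Input and 576996 and 565176 in Ribo. Cells with the control hairpin, shScramble, gave 807605 and 1477297 counts in Input and 392160 and 413823 in Ribo. Cells with a hairpin against EIF4E2, sheIF4E2, gave 2484833 and 1608662 in Input and 491714 and 546192 in Ribo. Between replicates, the Pearson correlation of log CPM across genes was 0.946 to 0.971 in Input and 0.863 to 0.957 in Ribo. Every fold change below has n = 2 cultures per group.

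EIF4E2 itself was 3.65-fold lower in RNA in the knockdown, but no change was detected in the resistant line. Its lower level under the hairpins was also a reason for using the first list of genes, so it is no independent check of the column labels. The gene (ENSG00000135930) lies on chromosome 2 at 232550659 to 232583644 in GRCh38. In the knockdown its RNA stood at 27.4% of control (log2 -1.87, SE 0.31, adjusted p = 8.08e-06), with 9.01 ± 3.14 CPM against 29.73 ± 10.35 (SD, n = 2). Without shScramble replicate 2 the log2 change was -1.38 with an adjusted p of 0.0903. Its footprints stood at 41.7% of control (log2 -1.26, SE 0.40), which did not pass the test (adjusted p = 0.0569). In the resistant line the RNA was at 49.52 ± 6.36 CPM in DDPr and 51.47 ± 0.94 CPM in Nor (SD, n = 2). That is a fold of 0.96 with a 95% interval of 0.726 to 1.27 (adjusted p = 0.918). The interval takes 1.96 SE to each side at n = 2 and may be too narrow, so it does not firmly exclude a larger RNA loss. Protein was not measured here. The footprints gave a fold of 1.27 (0.693 to 2.33, adjusted p = 0.851), and no change in its translational efficiency was detected in either experiment (adjusted p = 1 and 0.972). The change in EIF4E2 RNA differed between the experiments, by -1.79 (log2, knockdown minus resistant line, adjusted p = 0.00252).

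**Figure D1:**
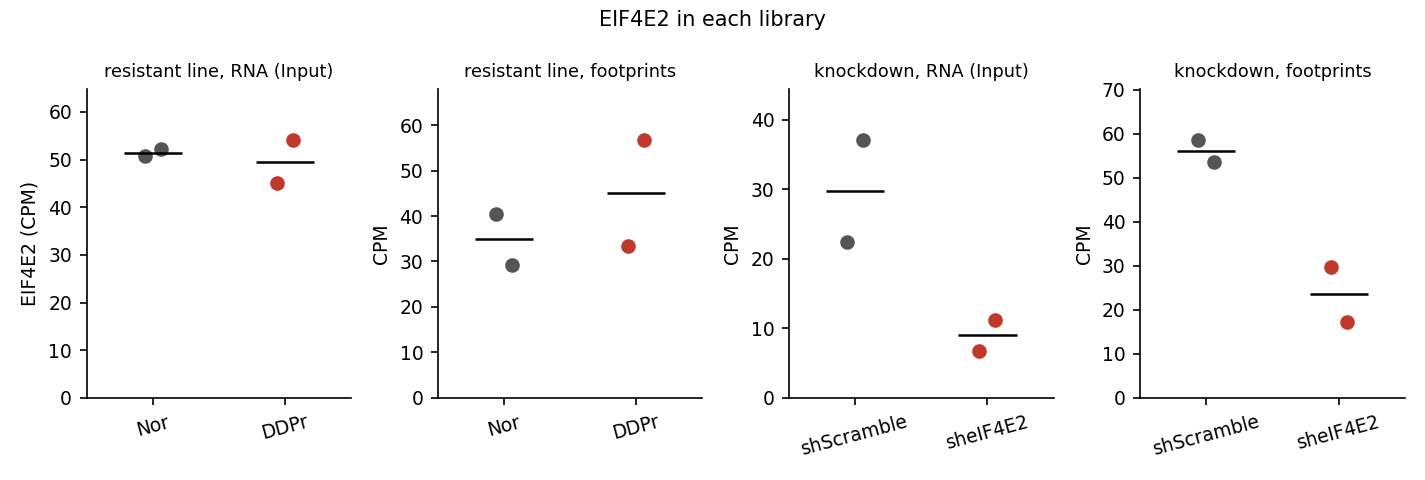
EIF4E2 level in CPM per library (points) with the mean of the 2 cultures of each line, for Input and Ribo libraries of both experiments. The sheIF4E2 Input libraries average 9.01 CPM against 29.73 in shScramble, while DDPr and Nor average 49.52 and 51.47.

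DIO2 and CRAT fell and GDF15 rose in RNA of the resistant line. DIO2, a selenoenzyme that activates thyroid hormone, fell from 135 ± 12 CPM in Nor to 1.11 ± 1.58 in DDPr (SD, n = 2; log2 -6.96, SE 0.38, adjusted p = 3.98e-14; chromosome 14, 80197526 to 80387757). CRAT, the mitochondrial carnitine acetyltransferase, had no reads in DDPr against 26.2 ± 3.75 CPM in Nor, at least 34.3-fold lower (adjusted p = 5.63e-08; chromosome 9, 129094142 to 129111189). The glutathione transferase GSTM2, CDYL2 and DLC1 also had no reads in DDPr and were at least 16.8-, 14.7- and 13.9-fold lower (adjusted p = 3.43e-05, 3.51e-05 and 4.85e-05). GDF15, a stress-induced cytokine, rose 10.6-fold, from 6.24 ± 4.48 to 70.9 ± 6.07 CPM (SD, n = 2; log2 3.41, SE 0.31, adjusted p = 2.17e-09; chromosome 19, 18374731 to 18389176). GREM1, a secreted BMP antagonist, GDA, which deaminates guanine, and WLS, needed for Wnt secretion, rose 9.06-, 8.89- and 7.36-fold (adjusted p = 0.000658, 6.59e-05 and 0.000358). These 9 genes were called whichever culture was left out.

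In all, 469 genes rose and 516 fell of 10905 tested in RNA (edgeR, Benjamini-Hochberg), 217 and 289 of them at least 2-fold. DESeq2 called 250 and edgeR with replicate as a block 1497. The number was 370 without Nor replicate 2 and 1319 without DDPr replicate 2. Of 85 genes named by the rule and called here, 41 were called in each of the 4 fits that left out 1 library, and 44 were lost in at least 1.

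Among called metallothionein, NRF2 and glutathione genes, decreases outnumbered increases in the resistant line. Both tested metallothioneins, which bind metals through cysteines, fell: MT2A 5.98-fold, from 210 ± 10.9 to 35.2 ± 4.62 CPM (SD, n = 2; adjusted p = 1.48e-11), and MT1X 3.84-fold (adjusted p = 0.00496; 0.171 without Nor replicate 1). Of 34 tested NRF2 and glutathione genes, 2 rose, 11 fell and 21 did not pass, and adjusted over the list alone 3 rose and 14 fell. The list was lower as a set (camera adjusted p = 8.08e-05; adjusted p = 0.435 with an estimated correlation). GPX2, a glutathione peroxidase, fell 6.81-fold (log2 -2.77, SE 0.23, adjusted p = 2.76e-10) and GSTM1 went from 64 counts to 1, a ratio of 66.9 with an exact counting interval of 11.6 to 2680 (adjusted p = 4.41e-06). GCLC, which limits the rate of glutathione synthesis, rose 2.29-fold (adjusted p = 0.00063). Among 13 platinum transport genes, the copper importer SLC31A1 rose 1.85-fold (adjusted p = 0.0094; 0.223 without Nor replicate 1), the volume-regulated anion channel subunit LRRC8A fell 2.74-fold (adjusted p = 7.14e-05), and 1 more fell (camera adjusted p = 0.0991).

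Of 28 Fanconi and homologous recombination genes 2 rose, among them FANCC, 2.06-fold (adjusted p = 0.00378; 0.108 without Nor replicate 1), and adjusted over the list alone 4 rose (camera adjusted p = 0.0616). In nucleotide excision repair 1 of 21 fell, ERCC6 (log2 -0.98, adjusted p = 0.0146; 0.42 without Nor replicate 1; camera adjusted p = 0.725). No mismatch repair gene of 7 passed the test (camera adjusted p = 0.727), with MSH6 at log2 -0.30 (adjusted p = 0.515). Of 23 p53 target genes 2 rose, GDF15 and GADD45A, a growth arrest gene (log2 1.13, adjusted p = 0.000994; 0.0534 without Nor replicate 2; camera adjusted p = 0.128). In the integrated stress response 5 of 26 rose and 1 fell, with the serine synthesis enzyme PSAT1 1.93-fold higher (adjusted p = 0.00223; 0.239 without Nor replicate 2; camera adjusted p = 0.101). Of 25 unfolded protein response genes 2 rose, XBP1 2.23-fold and SEC61B 2.01-fold (adjusted p = 6.56e-05 and 0.00129; camera adjusted p = 0.362). None of 22 BCL2 family and death regulators passed (camera adjusted p = 0.6), with MCL1 at log2 0.40 (adjusted p = 0.166). Of 31 proteasome genes 1 rose and 3 fell (camera adjusted p = 0.623).

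Of 77 cytosolic ribosomal protein genes 1 rose, 14 fell and 62 did not pass, and adjusted over the list alone 1 rose and 19 fell. Their median log2 change was -0.21 (camera adjusted p = 0.000105; adjusted p = 0.435 with an estimated correlation). RPL28 fell 2.09-fold, from 1822 ± 95.9 to 871.8 ± 32.6 CPM (SD, n = 2; adjusted p = 0.00042; 0.0634 without Nor replicate 1). Among 16 cap-binding and eIF4F factors, NCBP3 rose (log2 0.87, adjusted p = 0.0244; 0.52 without Nor replicate 1). The initiation factor EIF4G2 fell (log2 -0.68, adjusted p = 0.0119; 0.215 and 0.23 without Nor replicate 1 and 2), as did the eIF4E inhibitor EIF4EBP2 (log2 -0.52, adjusted p = 0.0404; 0.136, 0.492 and 0.184 without DDPr replicate 1 and Nor replicate 1 and 2; camera adjusted p = 0.0869). Of 27 eIF4E2 partners and repressors, ZNF598, which senses collided ribosomes, rose (log2 0.97, adjusted p = 0.00351; 0.0986 without Nor replicate 2) and the deadenylase subunit CNOT3 fell (log2 -1.12, adjusted p = 0.000281; camera adjusted p = 0.833). Of 4 mRNAs reported as eIF4E2-regulated, EGFR fell 1.71-fold, from 414.7 ± 14.9 to 243 ± 23.3 CPM (SD, n = 2; adjusted p = 0.0019; 0.105 and 0.0544 without Nor replicate 1 and 2). Of 20 aminoacyl-tRNA synthetases 1 rose and 3 fell, with YARS1 2.82-fold lower (adjusted p = 6.33e-05; camera adjusted p = 0.0655).

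Of 13 mitochondrially encoded genes 8 rose, and adjusted over the list alone 12 rose, with a median log2 change of 0.82, or 0.457 without DDPr replicate 2 (camera adjusted p = 3.41e-09; adjusted p = 0.438 with an estimated correlation). MT-ND3, a complex I subunit, rose 2.03-fold (adjusted p = 0.000143). Their share of protein-coding counts was 4.85 and 7.33% in the DDPr and 3.97 and 3.70% in the Nor Input libraries. Nuclear-encoded oxidative phosphorylation had 3 of 75 genes lower (camera adjusted p = 0.149), with the complex I subunit NDUFA3 2.22-fold lower (adjusted p = 0.00663; 0.0821 without Nor replicate 1). Of 20 glycolysis genes 4 fell, and adjusted over the list alone 1 rose and 7 fell (camera adjusted p = 0.00195; adjusted p = 0.498 with an estimated correlation). LDHB, a lactate dehydrogenase subunit, fell 5.18-fold (adjusted p = 0.000127). The 4 genes lie in runs of neighbouring genes that changed together, and over the 15 members outside these runs 0 were called and the median log2 change was -0.132, against -0.284 over all 20. In cholesterol synthesis 3 of 27 rose, such as SQLE (log2 1.24, adjusted p = 0.0161; 0.236 without Nor replicate 2; camera adjusted p = 0.0517). Of 27 hypoxia and HIF targets 1 rose, NDRG1 (log2 1.04, adjusted p = 0.0179; 0.28 without Nor replicate 1), and 1 fell (camera adjusted p = 0.533).

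Of 34 G2/M genes 4 fell, DLGAP5, a spindle protein, by 4.21-fold (adjusted p = 0.000988), and adjusted over the list alone 8 fell (camera adjusted p = 0.00319, 0.134 without DDPr replicate 1; adjusted p = 0.435 with an estimated correlation). Replication-dependent histones had 10 of 44 lower, such as H4C9 and H3C8, 3.17- and 2.08-fold (adjusted p = 8.65e-07 and 0.000127). Adjusted over the list alone 2 rose and 11 fell (camera adjusted p = 0.000862; adjusted p = 0.435 with an estimated correlation). Of 39 G1/S and replication genes 3 rose and 1 fell, with CDC45, a helicase component, 2.22-fold higher (adjusted p = 0.00268; camera adjusted p = 0.103). EGFR-MAPK signalling and feedback had 3 of 26 higher and 3 lower, such as DUSP5, an ERK phosphatase, 2.32-fold higher (adjusted p = 0.000296; 0.074 without Nor replicate 1) and EGR1, an immediate early gene, 3.8-fold lower (adjusted p = 0.00548; 0.0534 without Nor replicate 2; camera adjusted p = 0.874).

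Of 28 epithelial markers 5 rose and 2 fell, with the transcription factor ELF3 2.41-fold and CD24 2.27-fold higher (adjusted p = 2.61e-05 and 0.000317; camera adjusted p = 0.124). Of 21 mesenchymal markers 3 rose and 3 fell (camera adjusted p = 0.308). The membrane protease MMP14 went from 1 count to 31, a ratio of 29.6 with an exact counting interval of 4.94 to 1210 (adjusted p = 0.000975), while fibronectin, FN1, fell 4.16-fold and TGFB2 2.83-fold (adjusted p = 2.57e-06 and 0.00185). Squamous and neuroendocrine markers had 2 of 5 lower, KRT15 6.11-fold and TRIM29 2.24-fold (adjusted p = 0.000636 and 0.00129), and adjusted over the list alone 3 fell. As a set they were lower (camera adjusted p = 0.0211, 0.0974 without DDPr replicate 1; adjusted p = 0.435 with an estimated correlation). Of 14 interferon-stimulated genes 2 fell, SAMD9 5.16-fold and BST2 2.89-fold (adjusted p = 0.000974 and 0.000346; camera adjusted p = 0.613). Of 9 NF-kB and cytokine genes 1 rose (camera adjusted p = 0.198). No lung adenocarcinoma lineage marker of 5 passed (camera adjusted p = 0.183), with KRT7 at log2 0.29 (adjusted p = 0.432). The only tested marker of other cell types, CDH5, was at log2 0.52 (adjusted p = 0.515).

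None of the 7 lists called by camera in this comparison held with an estimated correlation, and none of the 19 camera calls over the 6 comparisons did. That setting rests on the spread between the 4 or 8 libraries of a comparison and was not run on simulated lists. A loss there cannot tell a weak list from a test with little power. The rotation test fry called 4 of the 7, but not glycolysis, G2/M or mitochondrially encoded genes (fry adjusted p = 0.126, 0.195 and 0.215). It also called 6 that camera did not: Fanconi and homologous recombination, p53 targets, hypoxia and HIF targets, cholesterol synthesis, G1/S and replication, and lung adenocarcinoma lineage (fry adjusted p = 0.0135 to 0.0427). In each of the other 5 comparisons fry called 0. In each list called, the median and mean had the sign of the test.

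Footprints of the resistant line changed in the same direction as RNA, with few genes past the test. DIO2 had no footprints in DDPr against 108.4 ± 8.26 CPM in Nor, at least 36.5-fold lower (SD, n = 2; adjusted p = 0.00377). OLFML3, a secreted olfactomedin, fell 13.9-fold (log2 -3.80, SE 0.40, adjusted p = 0.00377), GPX2 9.29-fold (log2 -3.22, SE 0.38, adjusted p = 0.00812) and MT2A 7.46-fold (log2 -2.90, SE 0.44, adjusted p = 0.0468). TLE1, a transcriptional corepressor, rose 6.44-fold, from 15.6 ± 1.23 to 101.4 ± 18.5 CPM (SD, n = 2; log2 2.69, SE 0.40, adjusted p = 0.0468; chromosome 9, 81583683 to 81689547). The other 2 calls were non-coding RNAs, outside the rule and chosen after their values were seen: LINC00942 with 1 count against 124 and H19 with 2 against 94 (adjusted p = 0.00377 and 0.0309). With DESeq2 TLE1 and MT2A did not pass (adjusted p = 0.653 and 0.237), nor did they among genes of at least 100 counts (0.118 and 0.136).

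That is 1 gene higher and 6 lower of 6375 tested, with 632 at an unadjusted p under 0.05. The spread between footprint replicates was wide, with a common biological coefficient of variation of 0.312 against 0.136 in RNA. Long non-coding RNAs took 15.0 and 17.4% of the counts in the DDPr and Nor Ribo libraries of replicate 1 but 30.1 and 26.4% in those of replicate 2. With replicate as a block 91 genes were called and among protein-coding genes alone 113. Without a single library the number was 31 (without DDPr replicate 2) to 128 (without Nor replicate 1). Of 749 genes called in RNA and tested in footprints, 725 had the same sign in both, 96.8% (95% Clopper-Pearson interval 95.3 to 97.9%). That interval takes genes as independent and does not cover the spread between cultures.

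As sets, 6 of 26 lists moved in these footprints by camera, each lost with an estimated correlation. Mitochondrially encoded genes were higher (median log2 0.75, camera adjusted p = 0.000115; adjusted p = 0.963 with an estimated correlation), with 0 of 13 called and 2 higher adjusted over the list alone. Lower were ribosomal proteins (0 of 73 called, camera adjusted p = 0.0023), NRF2 and glutathione (1 of 32, 0.00492; 3 adjusted over the list alone), nuclear-encoded oxidative phosphorylation (0 of 53, 0.00573) and histones (0 of 44, 0.0219). Fanconi and homologous recombination genes were higher (median log2 0.54, 0 of 9 called, camera adjusted p = 0.0254). With an estimated correlation these gave adjusted p = 0.963, and histones adjusted p = 0.977. All but the mitochondrial list were also lost when libraries were left out. Without DDPr replicate 1 and without Nor replicate 1 the adjusted p was 0.418 and 0.122 for ribosomal proteins, 0.297 and 0.122 for NRF2, 0.465 and 0.299 for oxidative phosphorylation and 0.496 and 0.935 for histones, whose median turned from -0.291 to 0.018 without Nor replicate 1. For the Fanconi list it was 0.0875 to 0.299 over the 4 libraries left out.

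No gene was called in translational efficiency in the resistant line. Of 6129 tested, edgeR and DESeq2 called 0, with 204 at an unadjusted p under 0.05 in edgeR. The fit with no filter on low counts called 3 genes, the fit with culture as a block 1, and the fit without Nor replicate 2 called 1. Neither cap-binding factors (median log2 0.18 over 14 genes, camera adjusted p = 0.427) nor any other of 26 lists was called. In simulated data, 83.3% of genes changed 4-fold were recovered and 13.4% of those changed 2-fold, so smaller changes were seldom recovered. Both assays were simulated at 1 shared spread, with a common coefficient of variation of 0.2 against 0.312 in footprints alone. At the spread of footprints alone 40.9% of 4-fold changes were recovered in footprints. The share of 83.3% is thus likely too high, and 4-fold changes in efficiency may have been missed.

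**Figure D2:**
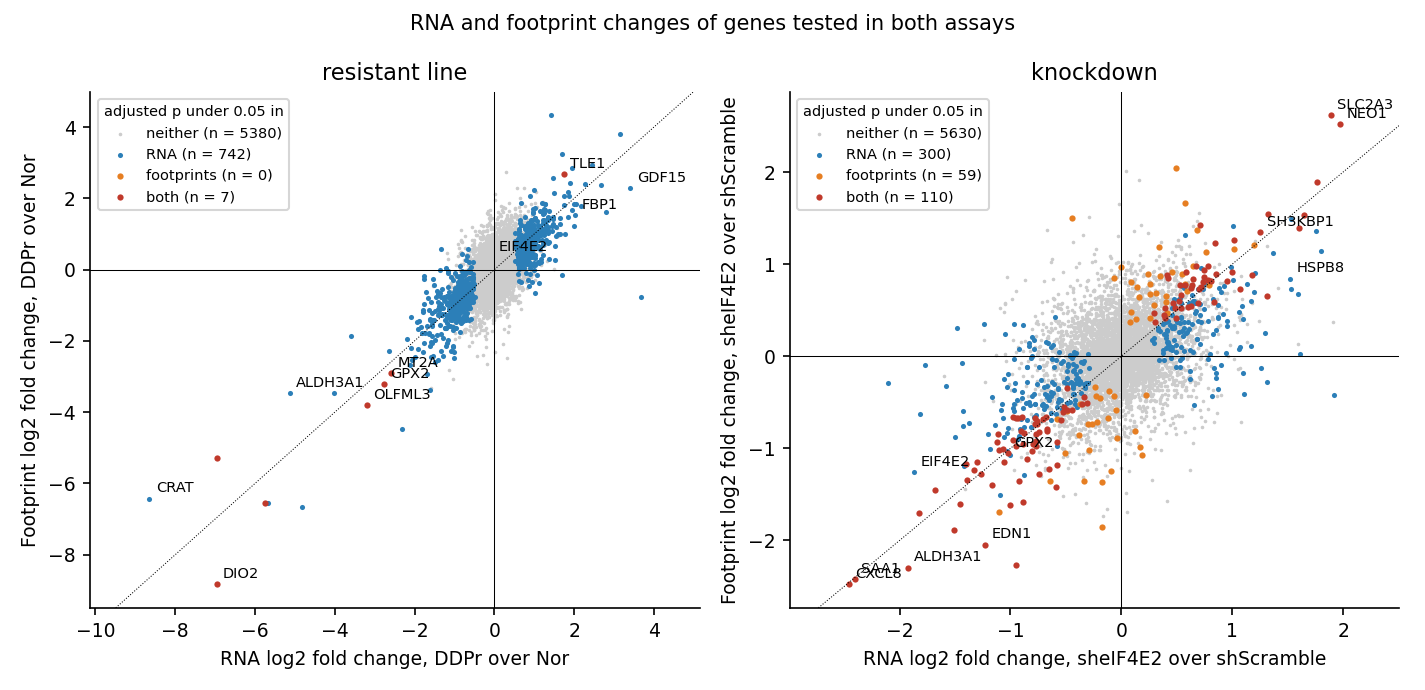
Log2 change in footprints against log2 change in RNA, 1 point per gene tested in both, for each experiment. The Pearson correlation across genes, which are not independent replicates, is 0.678 in the resistant line and 0.435 in the knockdown.

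CXCL8 and TNC fell and RNF144A rose in RNA of the knockdown. CXCL8, a neutrophil chemokine, fell 5.49-fold, from 39.2 ± 0.951 CPM in shScramble to 6.80 ± 1.68 in sheIF4E2 (SD, n = 2; log2 -2.46, SE 0.30, adjusted p = 1.17e-09; chromosome 4, 73740519 to 73743716), and was called whichever culture was left out. The matrix protein tenascin C, TNC, fell 8.64-fold (adjusted p = 1.7e-05; 0.112 without shScramble replicate 1), and the acute phase protein SAA1 5.3-fold (adjusted p = 1.78e-05; 0.221 without shScramble replicate 2). The complement protease C1S fell 7.53-fold (adjusted p = 0.000305; 0.0704, 0.0893 and 0.104 without sheIF4E2 replicate 2 and shScramble replicate 1 and 2), and LRR1, a subunit of a replisome ubiquitin ligase, 4.31-fold (adjusted p = 0.00295; 0.226, 0.216 and 0.0594 without sheIF4E2 replicate 1 and shScramble replicate 1 and 2). Among the genes that rose most, each was lost without 1 or more libraries. RNF144A, a ubiquitin ligase, rose 6.61-fold (adjusted p = 0.000986; 0.133 without sheIF4E2 replicate 1, 0.231 without shScramble replicate 2) and NEO1, a netrin receptor, 3.93-fold (adjusted p = 0.0036; 0.0728 without sheIF4E2 replicate 2, 0.116 without shScramble replicate 2). FAM110C rose 5.19-fold (adjusted p = 0.00396; 0.396 without sheIF4E2 replicate 1, 0.393 without shScramble replicate 2) and KLHL29 5.03-fold (adjusted p = 0.00582; 0.438 without sheIF4E2 replicate 1, 0.116 without shScramble replicate 1). The cadherin CDH4 rose 4.07-fold (adjusted p = 0.0114; 0.142, 0.152 and 0.323 without sheIF4E2 replicate 1 and 2 and shScramble replicate 2).

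In all, 236 genes rose and 319 fell of 9346 tested, 58 and 98 of them at least 2-fold. With every Input library thinned to 807605 counts, the smallest total, 106 rose and 133 fell. DESeq2 called 144, and the fits without 1 library called 277 (without sheIF4E2 replicate 1) to 406 (without shScramble replicate 1). Of 67 genes named by the rule and called here, 15 were called in each of the 4 fits that left out 1 library.

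Of 13 NF-kB and cytokine genes 8 fell and 5 did not pass, and adjusted over the list alone 9 fell, with a median log2 change of -0.59 (camera adjusted p = 9.34e-12; adjusted p = 0.581 with an estimated correlation). Of 33 NRF2 and glutathione genes 9 fell and 24 did not pass, and adjusted over the list alone 4 rose and 11 fell (camera adjusted p = 0.0132, 0.154 without sheIF4E2 replicate 2; adjusted p = 0.82 with an estimated correlation). GPX2 fell 2.03-fold (log2 -1.02, SE 0.18, adjusted p = 2.32e-05). Of 4 metallothioneins 2 rose, MT2A 1.46-fold (log2 0.55, SE 0.10, adjusted p = 1.7e-05) and MT1F, whose call was lost without any 1 of the 4 libraries (adjusted p = 0.105 to 0.442). None of the 2 tested in footprints was called. Of 27 epithelial markers 1 rose and 6 fell, the tight junction protein CLDN1 2.4-fold (adjusted p = 2.49e-05; camera adjusted p = 0.162). Of 20 mesenchymal markers 3 rose and 5 fell, TGFB2 1.86-fold (adjusted p = 4.47e-05; camera adjusted p = 0.162). Interferon-stimulated genes had 1 of 12 lower (camera adjusted p = 0.764).

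In knockdown RNA, EIF4E2 was the only one of 16 cap-binding factors called (camera adjusted p = 0.588). Of 26 partners and repressors, TNRC6B fell (log2 -0.81, adjusted p = 0.0162; 0.366 without sheIF4E2 replicate 1, 0.55 without shScramble replicate 2; camera adjusted p = 0.588). Of 3 tested eIF4E2-regulated mRNAs, EPAS1, which encodes HIF2A, rose 1.38-fold (adjusted p = 0.0019; 0.176 without sheIF4E2 replicate 1, 0.186 without shScramble replicate 2). The median log2 change over these 3 mRNAs was nevertheless negative, at -0.228. Among 76 ribosomal protein genes 3 rose, such as RPL37 (log2 0.50, adjusted p = 6.96e-05), and 3 fell, such as RPS24 (log2 -0.53, adjusted p = 0.000109; camera adjusted p = 0.815). No aminoacyl-tRNA synthetase of 20 was called (camera adjusted p = 0.815), with VARS1 at log2 -0.03.

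DNA repair, platinum transport and stress lists gave few calls. None of 19 nucleotide excision repair, 20 Fanconi and 7 mismatch repair genes passed (camera adjusted p = 0.632, 0.718 and 0.493), and 1 of 12 platinum transport genes fell (camera adjusted p = 0.815). In the integrated stress response 1 of 26 rose, the serine synthesis enzyme PHGDH 1.79-fold (adjusted p = 0.00013), and 2 fell (camera adjusted p = 0.963). Of 17 p53 target genes 1 rose (camera adjusted p = 0.986), of 24 unfolded protein response genes 1 rose and 1 fell (0.815), of 20 BCL2 family and death regulators 1 fell (0.815) and of 30 proteasome genes 1 fell (0.815).

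Of 26 hypoxia and HIF targets 4 rose and 3 fell (camera adjusted p = 0.493). Of these 7 calls, 2 lie in runs of neighbouring genes that changed together, and outside these runs 4 rose and 1 fell. The glucose transporter SLC2A3 rose 3.7-fold (adjusted p = 0.00202; 0.319 without sheIF4E2 replicate 1) and HIF1A fell (log2 -0.73, adjusted p = 0.0105; 0.118 without sheIF4E2 replicate 2, 0.48 without shScramble replicate 2). Glycolysis had 1 of 20 higher, nuclear-encoded oxidative phosphorylation 3 of 73 higher, and mitochondrially encoded genes 0 of 13 called (camera adjusted p = 0.418, 0.404 and 0.89). In cholesterol synthesis 2 of 27 rose and 2 fell (camera adjusted p = 0.885). RRM2, a ribonucleotide reductase subunit, rose 1.46-fold (adjusted p = 0.000345) as 1 of 38 G1/S and replication genes, of which 2 fell (camera adjusted p = 0.454). Of 34 G2/M genes 1 rose and 4 fell (camera adjusted p = 0.454), and no histone of 44 was called (0.493). The receptor tyrosine kinase MET fell 1.62-fold (adjusted p = 0.00207) among 25 EGFR-MAPK genes, of which 1 rose and 3 fell (camera adjusted p = 0.428). Lung adenocarcinoma lineage markers had 1 of 5 higher and 1 lower (camera adjusted p = 0.963), squamous and neuroendocrine markers 1 of 5 lower (0.815), and of 2 markers of other cell types the endothelial cadherin CDH5 fell 2.82-fold (adjusted p = 0.000724).

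CXCL8, SAA1 and ALDH3A1 fell in footprints of the knockdown. CXCL8 fell 5.57-fold, from 108.1 ± 5.1 to 19.6 ± 11.4 CPM (SD, n = 2; log2 -2.48, SE 0.35, adjusted p = 7.08e-09). SAA1 fell 5.35-fold (log2 -2.42, SE 0.33, adjusted p = 1.96e-09; chromosome 11, 18266260 to 18269977). The aldehyde dehydrogenase ALDH3A1 fell 4.91-fold, from 144.4 ± 4.84 to 29.3 ± 3.60 CPM (SD, n = 2; log2 -2.30, SE 0.29, adjusted p = 1.75e-10). These 3 were called whichever culture was left out, unlike the next 7. The chromatin protein HMGA2 fell 4.83-fold (adjusted p = 0.02; 0.295, 0.248, 0.172 and 0.472 without sheIF4E2 replicate 1 and 2 and shScramble replicate 1 and 2) and endothelin, EDN1, 4.13-fold (adjusted p = 0.00271; 0.0615, 0.118 and 0.0915 without sheIF4E2 replicate 1 and shScramble replicate 1 and 2). SLC2A3 rose 6.13-fold (adjusted p = 0.00236; 0.301, 0.148 and 0.138 without sheIF4E2 replicate 1 and 2 and shScramble replicate 1). NEO1 rose 5.75-fold (adjusted p = 0.0248; 0.298, 0.0858 and 0.412 without sheIF4E2 replicate 2 and shScramble replicate 1 and 2) and SMARCA2, a chromatin remodeller, 3.72-fold (adjusted p = 0.0139; 0.197, 0.342 and 0.299 without sheIF4E2 replicate 1 and 2 and shScramble replicate 1). TESMIN and ZNF512B rose 4.13- and 3.18-fold (adjusted p = 0.0481 and 0.0163), each lost without any 1 of the 4 libraries (adjusted p up to 0.713 and 0.31).

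Of 6460 genes tested in these footprints 83 rose and 89 fell, 19 and 37 of them at least 2-fold. DESeq2 called 26, and the fits without 1 library called 37 (without shScramble replicate 1) to 118 (without shScramble replicate 2). By list, 5 of 11 NF-kB and cytokine genes fell, 6 adjusted over the list alone, with a median log2 change of -0.93 (camera adjusted p = 1.27e-10; adjusted p = 0.539 with an estimated correlation). SOD2, the mitochondrial superoxide dismutase, fell 2.68-fold (log2 -1.42, SE 0.22). Histones were lower as a set, with 1 of 48 lower, and the same number adjusted over the list alone (median log2 -0.10, camera adjusted p = 0.0109, 0.251 without sheIF4E2 replicate 1 and 0.263 without shScramble replicate 2; adjusted p = 0.681 with an estimated correlation). NRF2 and glutathione genes had 4 of 34 lower, AKR1C1 1.63-fold, and 3 higher and 7 lower adjusted over the list alone (camera adjusted p = 0.078). Of 410 genes called in RNA and tested in footprints, 364 had the same sign in both, 88.8% (95% Clopper-Pearson interval 85.3 to 91.7%), and 110 were called in both in 1 direction. Here too the interval takes genes as independent and does not cover the spread between cultures.

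Translational efficiency changed for 1 gene in the knockdown. MT-ND6, the complex I subunit on the light strand of mitochondrial DNA (14149 to 14673), was 1.56-fold lower in footprints relative to RNA (log2 -0.65, SE 0.14, adjusted p = 0.0179). It was lost without sheIF4E2 replicate 1 (adjusted p = 0.177), sheIF4E2 replicate 2 (0.644) or shScramble replicate 1 (0.557). The 13 mitochondrially encoded genes were lower in translational efficiency as a set (median log2 -0.27, 1 called and 7 adjusted over the list alone, camera adjusted p = 1.55e-09, 0.531 without sheIF4E2 replicate 2; adjusted p = 0.856 with an estimated correlation). That median was -0.088 without sheIF4E2 replicate 2 and -0.423 without sheIF4E2 replicate 1. Their footprints were lower too (median log2 -0.21, 2 of 13 called and 8 adjusted over the list alone, camera adjusted p = 2.73e-06, 0.137 without sheIF4E2 replicate 2; adjusted p = 0.681 with an estimated correlation), with a median of -0.12 and -0.336 without the same libraries in turn. They took 2.97 and 2.93% of coding footprints in the shScramble and 2.76 and 2.41% in the sheIF4E2 libraries. Whether Ribo reads of mitochondrially encoded genes mark translating ribosomes was not tested, so these values do not establish a change in mitochondrial translation. Of 6099 genes tested 367 had an unadjusted p under 0.05, DESeq2 called 0, and the fit with culture as a block called 0. Cap-binding factors (median log2 0.08 over 14 genes, camera adjusted p = 0.721) and the partners and repressors of eIF4E2 (median log2 0.05 over 20, 0.502) were not called. In simulated data, 87.9% of genes changed 4-fold and 37.3% of those changed 2-fold were recovered. Both assays were again simulated at 1 shared spread, with a common coefficient of variation of 0.051 against 0.066 in footprints alone.

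**Figure D3:**
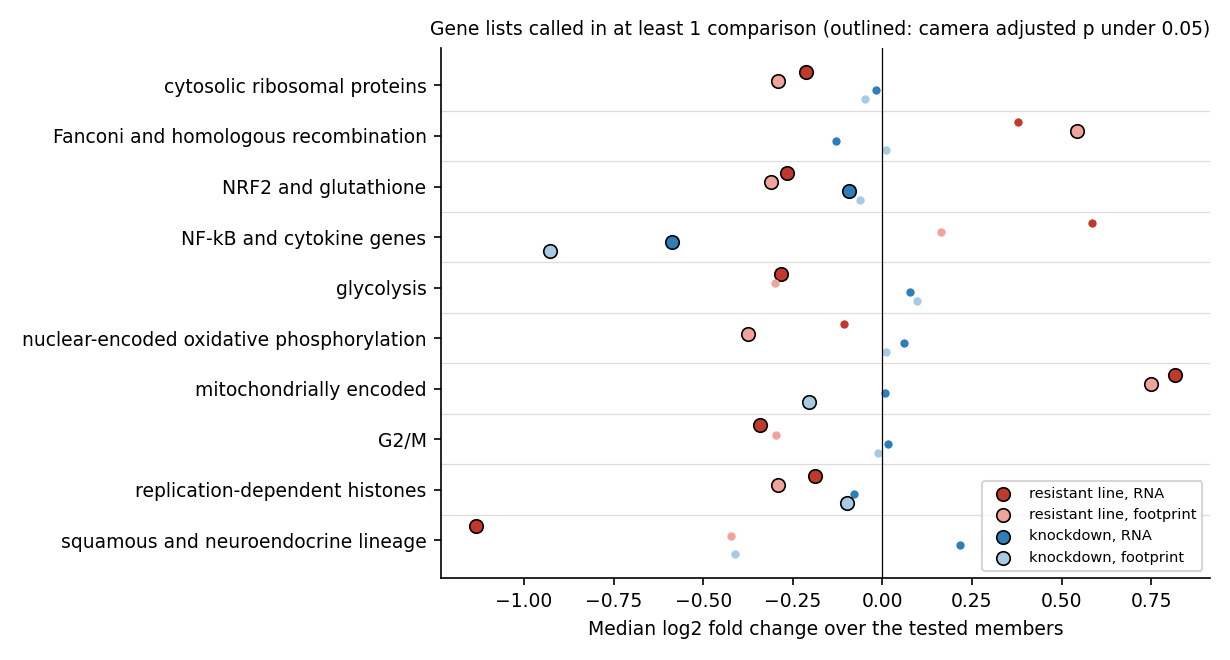
Median log2 change in RNA and footprints of both experiments, for gene lists called in at least 1 of these comparisons. Calls by camera at its preset correlation are outlined. NF-kB and cytokine genes stand at -0.59 in knockdown RNA and -0.93 in its footprints, and mitochondrially encoded genes at 0.82 in RNA of the resistant line.

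More genes moved in 1 direction in both experiments than independent lists would share. Among 9133 genes tested in RNA in both, 36 rose in both against 10.49 for independent lists (one-sided Fisher exact p = 5.5e-11), and 60 fell in both against 15.76 (exact p = 4.88e-20). Opposite calls numbered 21 and 17 against 13.93 and 11.86 (exact p = 0.0395 and 0.0854). The 36 increases include the small non-coding RNA entries RN7SKP48, RN7SKP25, RN7SKP185, RN7SKP86, RN7SKP217, RN7SKP180, RNU4-82P and SNORD3B-1. Entries of 1 family may carry 1 signal counted more than once. The Fisher test treats genes as independent, so its p describes the lists only. ALDH3A1 fell 35.0-fold in the resistant line and 3.8-fold in the knockdown (adjusted p = 5.27e-12 and 3.8e-09), and the nuclear receptor NR0B1 12.1- and 3.51-fold (adjusted p = 2.28e-05 and 1.3e-05). The keratin KRT4 fell 16.3- and 7.83-fold (adjusted p = 1.11e-07 and 0.000908; 0.166 in the knockdown without sheIF4E2 replicate 2). MYPN and DLGAP5 also fell in both, with knockdown calls lost without shScramble replicate 2 (adjusted p = 0.193 and 0.377). Higher in both was the small heat shock protein HSPB8, 3.21- and 2.88-fold (adjusted p = 0.00534 and 0.000139; 0.154 in the resistant line without Nor replicate 1). The adaptor SH3KBP1 rose 2.32- and 2.39-fold (adjusted p = 0.000723 and 0.000142; 0.0685 in the knockdown without sheIF4E2 replicate 1) and the gluconeogenic enzyme FBP1 4.07- and 2.25-fold (adjusted p = 7.69e-08 and 0.0381; up to 0.485 in the knockdown, without sheIF4E2 replicate 1). ASL and NDRG1 completed the 5 largest shared increases. The shared number in 1 direction was 49 without shScramble replicate 2, and DESeq2 gave 17. Across all genes the 2 changes had a Pearson correlation of 0.14. In footprints GPX2 was the 1 gene called in both (0.06 for independent lists, p = 0.0573 by the same exact test), and its knockdown call was lost without sheIF4E2 replicate 1 (adjusted p = 0.21) or shScramble replicate 1 (0.172).

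Many genes changed by unequal amounts. The RNA change differed between experiments for 538 of 9133 genes, 303 with a more positive and 235 with a more negative change in the knockdown, and the footprint change for 70 of 4733. These numbers were 239 to 838 and 13 to 143 when 1 library was left out. No difference in translational efficiency passed among 4721 genes (edgeR, 214 at an unadjusted p under 0.05). MT2A had the smallest p, lower in the resistant line and higher in the knockdown (difference 3.13 in log2, adjusted p = 1.42e-12). Of 133 named genes tested 49 differed in RNA, and of 87 in footprints 9.

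Some runs of neighbouring genes changed together. Windows of 20 neighbouring protein-coding genes were set up after the changes were seen, and a window counted where its median log2 RNA change was at least 0.4 in size. The resistant line had 58 such windows of 453, 26 higher and 32 lower, against at most 6 in 1000 shuffles of gene positions. They held 12.8% of the genes in windows and 290 of 824 called genes, 35.2%. The end of chromosome 19 (57280051 to 58316812) had all 20 genes lower (median log2 -1.44), as had chromosome 9 from 128411751 to 129636135 (median log2 -0.999), which holds CRAT and LRRC8A. Chromosome 22 from 21642302 to 25197448 had all 20 higher (median 0.89). Also inside such windows lie GPX2, TLE1, GAPDH, LDHB, XBP1, CDC45, YARS1, RPL28, CNOT3, FBP1, SLC31A1, FANCC, H4C9 and H3C8. All 4 called glycolysis genes, all 4 called proteasome genes and 7 of 10 called histones were in them, against 3 of 13 called ribosomal protein and 3 of 13 called NRF2 genes that have a window. The knockdown had 7 windows of 396, 1 higher and 6 lower, against at most 2 in the shuffles, with 43 of 464 called genes. Both experiments had a higher window on X (17737449 to 24550466 and 12791355 to 23686397). Both also had a lower window on chromosome 10 (16436943 to 27187953 and 20779973 to 32056425) and lower windows on chromosome 14, where DLGAP5 and PSMA3 lie. The chromosome 10 window had the largest change among the 7 of the knockdown (median log2 -0.657, against -0.475 in the resistant line).

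**Figure D4:**
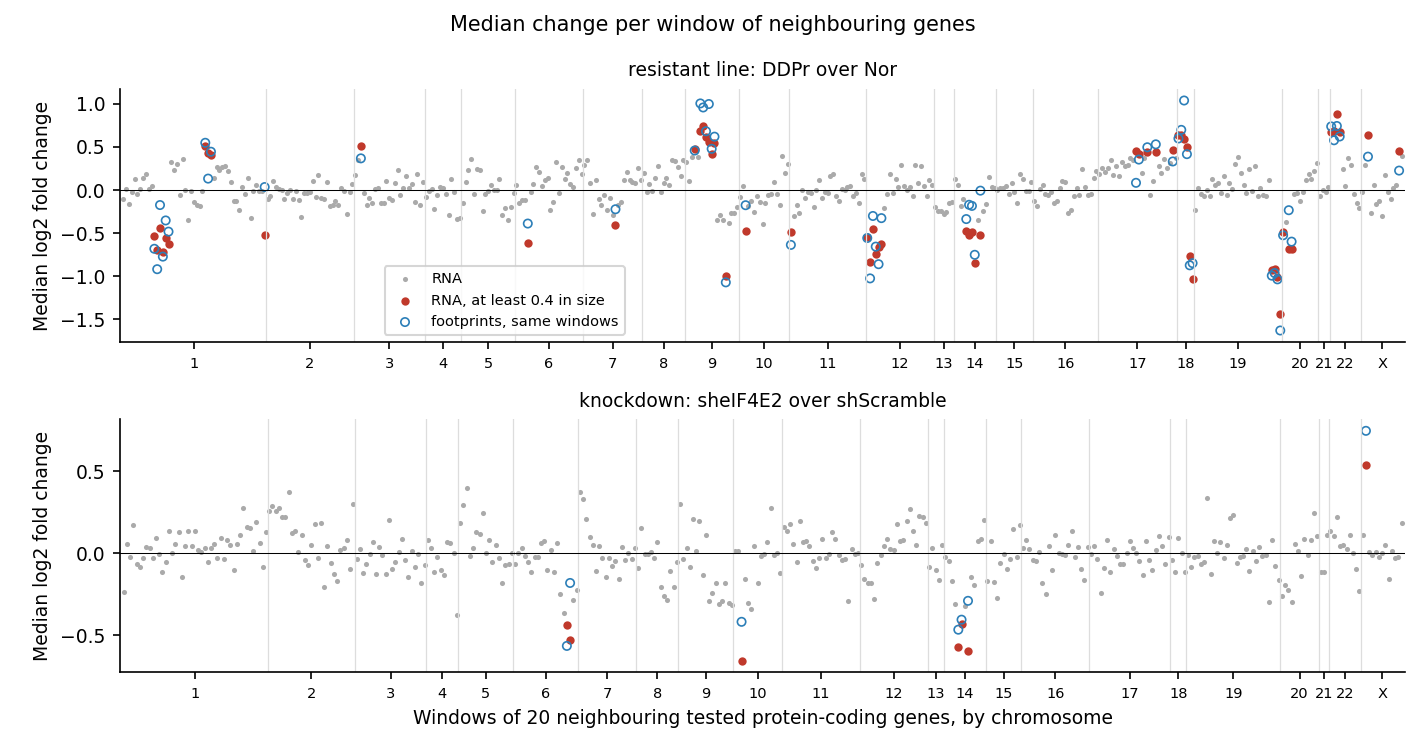
Median log2 RNA change of windows of 20 neighbouring protein-coding genes along the genome, by chromosome, for each experiment. Windows at or beyond 0.4 in size number 58 in the resistant line and 7 in the knockdown.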

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

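The tests on the last parts of the tables, on chance runs of neighbouring genes, on copy number and on NRF2 targets were chosen after the result was seen. Those on single hairpin or control libraries, gene length, shared blocks and depth were written before their results, but the length test first took coding length by mistake and was corrected to exon length after its result was seen, which lowered the shares kept.

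Both knockdown tables hold a second set of lines after the first, which was not used in any comparison. Their log ratios of knockdown to control ran against those of the first part as labelled, with a correlation across genes of -0.96 in Input and -0.856 in Ribo. If the 2 parts came from different libraries, few genes should hold the same 4 counts. Yet of the Input genes with unequal groups in both parts, 98.1% had equal counts once control and knockdown columns were exchanged. In Ribo 17.1% had, but there the last part lists longer intervals (median 4143 bases against 1311 over shared genes), so this share alone cannot decide. Yet 1459 of 8514 Ribo genes had equal counts after the exchange, against 3 as labelled. The correlation of log ratios, over 2378 genes with at least 100 counts, only changes sign with the exchange, to 0.856, and adds no evidence. For those 1459 genes the equal counts argue against different libraries in Ribo too. If the first part held the exchanged columns, EIF4E2 should be higher under its hairpins there, and its log2 change was -1.867, so exchanged columns in the last Input part remain a candidate explanation, with no biological one tested.

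Runs of neighbouring genes changed together in RNA in both experiments. Chance runs are argued against by 58 windows in the resistant line and 7 in the knockdown, against at most 6 and 2 in 1000 shuffles, and gene length by 96.6% and 85.7% of them kept once a trend in exon length and level was removed. The knockdown windows do not come from 1 library, as the weaker hairpin moved them by 0.511 and the weaker control by 0.528 (median log2, signed as in the fit). In the resistant line, gene copy number that differs between the lines may explain them, since footprints followed RNA with a slope of 0.965 (SE 0.043), and 1.419 (SE 0.153) over the 32 lower windows alone. The knockdown slope of 0.996 (SE 0.179) contrasts 1 higher window with 6 lower ones, over which alone it was -0.415 (SE 0.728), so copy number stays open there. Regulation of whole regions would give slopes like those of copy number and was not tested, base composition was not tested, and cells that drifted apart in culture would carry such differences whether or not eIF4E2 was lowered.

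More genes, related small non-coding RNA entries among them, were called in the same direction in both experiments than independent lists would share. Shared chromosome blocks do not account for all of this. Without the genes in block windows of either experiment, shared increases went from 36 to 28 and shared decreases from 60 to 35. The remaining shared calls were at least 3.61 times those of independent lists in each direction. Unequal depth of the knockdown groups does not account for the excess, as with the libraries thinned to 807605 counts the ratio was at least 3.86. Lower expression of NRF2 targets stays open as a part of it. AKR1B10, AKR1C1, GPX2 and UGDH, 4 of the 60 shared decreases, were lower in both, but the list had been seen lower in each experiment, and with 10 and 9 of its 33 members lower 2.73 would be shared by chance (Fisher exact p = 0.252). Growth state or drift in culture was not tested.

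Changes that differed between the experiments, by a test of the difference itself, numbered 538 genes in RNA and 70 in footprints. In RNA, the knockdown change minus the resistant change was 3.127 for MT2A, 5.884 for DIO2, 3.19 for ALDH3A1, 1.75 for GPX2, 1.279 for FN1 and 0.967 for LRRC8A (log2). It was -2.222 for ELF3, -2.193 for CD24 and -1.79 for EIF4E2. The footprint difference of GPX2 was 2.163. Lists whose RNA changes differed by camera had median differences of 0.225 for cytosolic ribosomal proteins, -0.671 for Fanconi and homologous recombination, -0.316 for epithelial markers and -0.789 for NF-kB and cytokine genes. For glycolysis the median was 0.464, for nuclear-encoded oxidative phosphorylation 0.259, for mitochondrially encoded genes -0.749 and for replication-dependent histones 0.144. In footprints these were 0.298 for ribosomal proteins, -0.542 for NF-kB and cytokine genes, 0.399 for glycolysis, 0.361 for oxidative phosphorylation and -1.049 for mitochondrially encoded genes, and in translational efficiency -0.291 for the last. With an estimated correlation none of these list differences passed (adjusted p of at least 0.263 in RNA, 0.658 in footprints and 0.971 in translational efficiency), while fry called 7 of the 8 in RNA, all but the mitochondrial list, and 0 in the others.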

How the results depend on the processing

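The fit on protein-coding genes only, every alternative for genes called in both RNA and footprints, and the left-out libraries for gene lists, calls shared by the experiments and differences between them were chosen after the data were seen, and the other settings were chosen before the data were examined. The cause was not tested for any of the values below, apart from the fewer samples in fits that leave 1 out, where the lone sample is assumed to vary like the other groups. Named genes that were called kept their direction wherever an alternative gave them a value (2167 values, with 125 missing where a gene was filtered out or got no adjusted p), with 1710 values on the same side of the threshold and 457 no longer past it. In RNA of the resistant line the replicate block gave 1497 calls, the joint fit of both assays 192 and DESeq2 250, and leaving out 1 library 370 (Nor replicate 2) to 1319 (DDPr replicate 2). In its footprints there were 14 calls with no filter on low counts, 4 with at least 100 counts, 91 with the replicate block, 125 in the joint fit and 113 among protein-coding genes, and 31 (without DDPr replicate 2) to 128 (without Nor replicate 1). Its translational efficiency gave 3 calls with no filter, 1 with culture as a block and 0 to 1 without 1 library (1 without Nor replicate 2). Knockdown RNA gave 144 calls with DESeq2 and 277 (without sheIF4E2 replicate 1) to 406 (without shScramble replicate 1), and its footprints 26 with DESeq2 and 37 (without shScramble replicate 1) to 118 (without shScramble replicate 2). Translational efficiency in the knockdown gave 0 with culture as a block, 0 with DESeq2 and 0 to 1 without 1 library. Of the gene lists, 0 passed in any comparison with an estimated correlation, a setting whose power was not tested on simulated lists. The fry test gave 0 apart from 10 in RNA of the resistant line and 15 for the RNA difference between the experiments. The histone list in its footprints went from a median of -0.291 to between -0.519 (without DDPr replicate 2) and 0.018 (without Nor replicate 1). Without 1 library the lists called numbered 5 to 11, 1 to 7 and 0 to 2 in RNA, footprints and translational efficiency of the resistant line, and 1 to 3, 2 to 6 and 0 to 1 in the knockdown. EIF4E2 in the resistant line ranged without 1 library from -0.192 to 0.075 in RNA (0.075 without DDPr replicate 1) and from -0.1 (without DDPr replicate 2) to 0.708 in footprints, none past the test. In the knockdown its RNA ranged from -2.186 to -1.383, past the test except without shScramble replicate 2 (adjusted p = 0.0903), its footprint change was -1.267 in the joint fit (adjusted p = 0.0372), and its translational efficiency ranged from -0.228 (without sheIF4E2 replicate 1) to 1.272. Genes called in RNA and footprints in the same direction numbered 14 with no filter, 4 with at least 100 counts, 77 with the replicate block, 75 in the joint fit, 102 among protein-coding genes and 21 to 53 without 1 library in the resistant line, and 21 with DESeq2 and 31 to 53 without 1 library in the knockdown. Calls in the same direction in both experiments numbered 148 at an adjusted p under 0.1, 17 with DESeq2 and 49 (without shScramble replicate 2) to 118 in RNA, and 2, 0 and 0 to 10 in footprints, with 11 among protein-coding genes. Differences between the experiments numbered 239 (without shScramble replicate 2) to 838 (without DDPr replicate 2) in RNA, 13 (without shScramble replicate 1) to 143 (without Nor replicate 1) in footprints and 0 to 1 in translational efficiency.

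At this depth and spread, small changes were least often recovered in footprints of the resistant line. In simulated data with the spread of each comparison, 2-fold changes were recovered for 35.8% of genes in RNA and 1.5% in footprints of the resistant line, and for 56.7% and 61.2% in the knockdown. At 4-fold these shares were 95.5%, 40.9%, 98.5% and 98.5%.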

Other observations

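The genes below fall outside the rule for named genes in the comparison given and were chosen after their values were seen. In RNA of the resistant line the non-coding RNA LINC00942 was at 1.5 ± 0.54 CPM against 84.98 ± 2.23 in Nor (SD, n = 2; log2 -5.74, SE 0.35, adjusted p = 3.87e-13), and H19 had 1 count against 149, a ratio of 156 with an exact counting interval of 27.5 to 6190. The lysosomal protease CTSC was 16.3-fold and OLFML3 9.18-fold lower, and the actin crosslinker FLNC was 6.96-fold higher, each called whichever culture was left out. In the knockdown the siderophore-binding protein LCN2 was 3.55-fold lower in RNA and 3.25-fold lower in footprints, complement C3 2.85- and 3.7-fold lower and the mucin MUC4 2.47-fold lower in RNA, each called whichever culture was left out. LPCAT1, an enzyme of phospholipid remodelling, was 2.02-fold higher in RNA and 2.4-fold higher in footprints.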
